A study of Homo sapiens with 12 samples.

How the data were processed

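22Rv1 cells were grown for 40 h in 2 to 3 plates per condition, treated for 4 h with 0.04% DMSO or with 20 µM SKBG-1(R) or SKBG-1(S) in 0.04% DMSO, and crosslinked with 400 mJ of UV light, per the labels' protocols. NONO was immunoprecipitated with a rabbit antibody and single-end libraries were made by the eCLIP method and sequenced on a NovaSeq. Groups and replicate numbers were taken from the sample titles. Each of the 3 groups had 2 immunoprecipitation libraries, each with its input library, 12 libraries in all.

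The authors deposited 1 peak list per replicate, called for each immunoprecipitation against its own input and not on pooled replicates. Per the submitters' processing notes, cutadapt 1.9 and STAR 2.4.0i were used, and the notes name both hg19 and hg38. The peak caller and its version are not given in the sources used here. The deposited values per peak are a −log10 p of immunoprecipitated reads against input and a log2 enrichment over input. Both are the authors' own and were used only to filter, rank or describe peaks within a list. The deposited −log10 p had a minimum of 3 and a cap of 400, which 47 peaks reached, and the deposited log2 enrichment a minimum of 3. All 26351 peaks met both limits, so the enriched peaks analysed are the deposited lists. Each peak carries the authors' annotation to a gene and a class of region. The build is GRCh38: of 9850 transcripts in the annotation, 9781 (99.3%) had the same coordinates within 1 nt in GENCODE 29, which gave gene positions and identifiers for all 1689 gene names. A further 1.31% of peaks were annotated to 2 or more overlapping genes and kept under the joint name.

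No read counts were given. The depth of each library is therefore unknown, and the number of peaks in a list, 669 to 14847, sets the precision. From the steps between values of enrichment, which follow single reads where the input stood at its lowest value, the immunoprecipitation to input read ratio was estimated at 2.96 to 3.92. Between 61.9 and 83.9% of a list's values lay within 0.02 of a step. Shares of peaks have 95% Wilson intervals, which cover counting error only.

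Group comparisons of single values (the log2 number of peaks, the share in introns and the median position of intronic peaks along their gene) used exact two-sided permutation tests of 2 lists against 2, which cannot give a p below 0.333. For genes, peaks per 10000 peaks of the list were tested on the log2 scale with a prior count of 2, scaled to the list size, by limma with a trended prior variance. All 6 lists were in 1 fit so that the 3 groups shared an estimate of the spread. Tested were 479 genes with at least 10 peaks over the lists, at a Benjamini-Hochberg threshold of 0.05. Gene lists with at least 3 tested members were tested by camera with a correlation of 0.01, by camera with an estimated correlation, and by fry. The lists were nuclear long noncoding RNAs, snoRNA host genes, paraspeckle proteins, splicing factors, polyadenylation and transcription factors, cell cycle and DNA repair, prostate cancer drivers, electrophile and heat stress, neuroendocrine markers, markers of other cell types, ribosomal proteins, transcripts of the mitochondrial genome and replication-dependent histones. The design, these lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison, the 10 genes higher and the 10 lower with the smallest p among genes that moved the same way in both same-numbered pairs of lists. It adds members of the lists by number of peaks, the 5 strongest regions in both lists of a group and no other, and NONO. The genes called by other tests, the genes with the most peaks over all lists, the 10 genes absent from SKBG-1(R), and SFPQ, PSPC1, KLK3 and KLK2 were named after their values were seen.

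Peaks overlapped when they shared at least 1 nt on the same strand. Shuffled overlap was the mean of 100 seeded shuffles of peaks to uniform places within their annotated genes. The shuffles did not keep the class of region or the clustering of peaks along a gene, so they can understate chance overlap. Peaks of all lists were merged into regions where they overlapped. A gene counted as bound in a group when both of its lists held a peak.

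The gene test was tested on simulated lists drawn for the 479 genes from the real means and list sizes, for SKBG-1(R) against DMSO, with 200 genes changed. With the spread set near that of the data (residual SD 0.91, against 0.94 in the data) it called 2% of genes changed 4-fold, 35% of those changed 16-fold and 53% of those changed 64-fold, with 0, 0 and 2 false calls. With little spread it called 67% of genes changed 16-fold, which missed a target of 80% set for the test. The missing calls were taken to be genes with few peaks, and the requirement was changed to the 100 genes with the most peaks, of which 40 were changed and 100% were called.

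The alternatives were stricter limits (log2 enrichment of at least 4, −log10 p of at least 5), lists reduced to equal size, widths of peaks in place of their number, a prior count of 0.5, no filter or at least 30 peaks per gene, TMM scaling or none, voom weights, the Cochran-Mantel-Haenszel exact test, only the lists of the contrast, the replicate number as a block, leaving out each list, and an overlap of 50% of the shorter peak. All deposited peaks in place of the enriched ones is the same analysis here and was not repeated. Lists of equal size with the block, and stricter limits for gene lists, were added after the data were examined. Leaving out a list leaves its group with 1 list, which is assumed to vary like the other groups. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Some genes that the rule picks, and 1 further gene list that entered the adjustment over lists, are not reported here.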

Results

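NONO is a nuclear RNA-binding protein of paraspeckles, the nuclear bodies built on the long noncoding RNA NEAT1. Its RNA contacts were mapped by eCLIP in 22Rv1, a human prostate cancer cell line. In eCLIP, proteins are crosslinked to RNA by UV light, the protein is immunoprecipitated, and the RNA fragments are sequenced beside an input library of the same cells. Cells received 0.04% DMSO alone, or SKBG-1(R) or SKBG-1(S) at 20 µM, for 4 h. The 2 compounds are the stereoisomers of SKBG-1, and the study's title places them among small molecules that target NONO. Each of the 3 treatments had 2 replicates, each with 1 immunoprecipitation and 1 input library, so that 12 libraries gave 6 peak lists. The comparisons ask whether either compound altered where NONO contacts RNA, and whether the stereoisomers differed. RNA-seq libraries and NONO-knockout cells, which the design also names, are not analysed here.

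The 6 lists held 26351 peaks, every one enriched at least 8.0-fold over input with a −log10 p of at least 3. The DMSO lists held 669 and 3678 peaks for replicates 1 and 2, the SKBG-1(R) lists 1953 and 14847, and the SKBG-1(S) lists 1237 and 3967. In every group the replicate 2 list was the longer, by 5.5-fold for DMSO, 7.6-fold for SKBG-1(R) and 3.21-fold for SKBG-1(S). The lists give no read totals, so sequencing depth is unknown and a gene absent from a list is not shown to be unbound. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

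**Figure D1:**
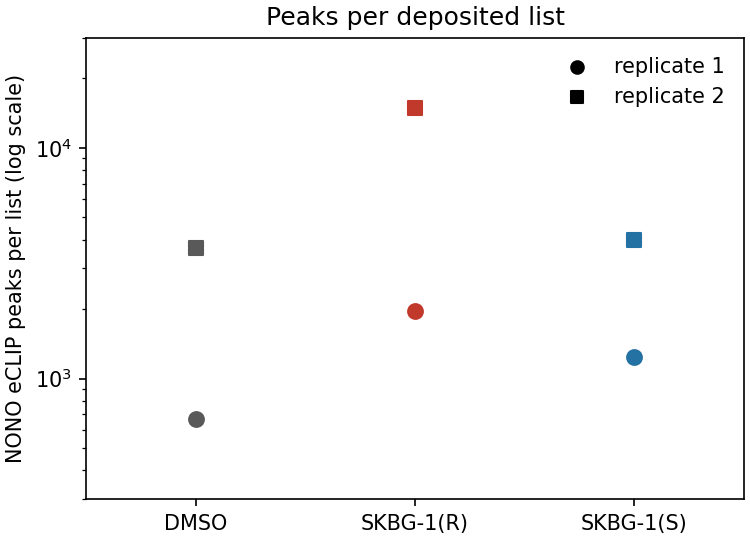
Number of NONO eCLIP peaks in each of the 6 lists, on a log axis. Circles are replicate 1 and squares replicate 2. The SKBG-1(R) replicate 2 list, with 14847 peaks, stands above all others, and the DMSO replicate 1 list, with 669, below them.

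In all groups most NONO peaks lay in introns. MIRLET7BHG, the host transcript of let-7 microRNAs, led every list but DMSO replicate 2 (C22orf34, 137 peaks) and SKBG-1(S) replicate 2 (ANKRD11, 84). Pooled over the 6 lists, which differ in length, it held the most peaks, with 662, of which 365 were in SKBG-1(R) replicate 2. It was followed by the noncoding C22orf34 with 567, GSE1, which encodes a subunit of a histone demethylase complex, with 498 (358 of them in SKBG-1(R) replicate 2 and 2, 2 and 7 in the replicate 1 lists), ANKRD11, a chromatin regulator, with 459, and SLC7A5, a transporter of large neutral amino acids, with 399. All 6 lists held a peak in 101 of 16419 merged regions. A region joins peaks in a chain, so the 6 need not share a single site, and its enrichment is the highest of each list within it. The strongest of these by its weakest list was in a proximal intron of NFIX, a nuclear factor I transcription factor, on chromosome 19 from 12995870 to 12996254 (GRCh38), where the authors' log2 enrichment was 4.47 to 6.30. Others lay in introns of ANP32A on chromosome 15 (68818665 to 68818908), SSBP2 on chromosome 5 (81750281 to 81750558), and BCOR, a Polycomb-associated repressor, on chromosome X (40092057 to 40092296). The paraspeckle RNA NEAT1 held 1 peak in SKBG-1(R) replicate 1 and 1 in SKBG-1(S) replicate 1, and MALAT1, its neighbour in the genome, 1 in DMSO replicate 1 and 1 in SKBG-1(S) replicate 1. Transcripts of NONO itself, of its partners SFPQ and PSPC1, and of the prostate kallikreins KLK3 and KLK2 held 0 peaks in every list, which in lists of peaks above a minimum sets no limit on their binding.

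By the authors' annotation, introns held 87.4% (95% Wilson interval 84.7 to 89.7) and 91.3% (90.3 to 92.1) of the DMSO peaks. They held 87.8% (86.3 to 89.2) and 90.4% (89.9 to 90.9) of the SKBG-1(R) peaks and 89.9% (88.1 to 91.5) and 89.6% (88.6 to 90.5) of the SKBG-1(S) peaks. 5′ UTRs held 8.07% and 5.0% of the DMSO peaks, 7.83% and 4.30% of the SKBG-1(R) peaks, and 5.98% and 6.02% of the SKBG-1(S) peaks. Coding exons held 1.06 to 2.24% per list and 3′ UTRs 0.30 to 1.58%. Introns next to splice sites, the authors' proximal class, held 35.4% in DMSO replicate 1 and 22.6% in replicate 2, 41.1% and 18.6% with SKBG-1(R), and 39.5% and 30.1% with SKBG-1(S). The Wilson intervals cover counting error only. Intronic peaks clustered towards the start of genes, with position running from 0 at the 5′ end to 1 at the 3′ end. Their median position was 0.083 and 0.217 in DMSO, 0.042 and 0.288 in SKBG-1(R), and 0.087 and 0.157 in SKBG-1(S). With lists of equal size the medians were 0.083 and 0.107, 0.012 and 0.408, and 0.067 and 0.039. The clustering was thus weakest in SKBG-1(R) replicate 2.

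**Figure D2:**
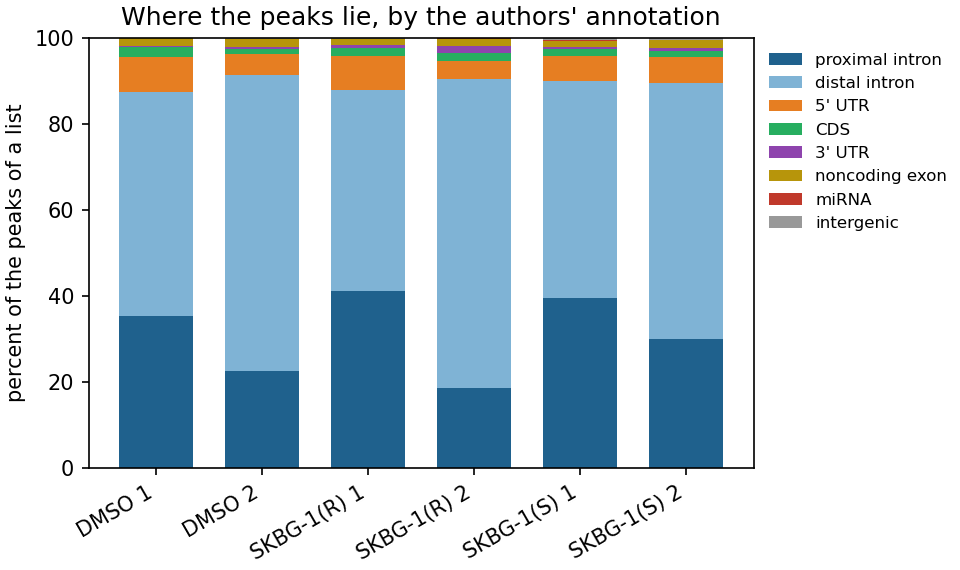
Percent of the peaks of each list in each class of region, by the authors' annotation. Numbers after the group name are replicates. Introns, in both blues, hold 87.4 to 91.3% of every list, and the proximal part is smaller in replicate 2 than in replicate 1 of every group.

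Replicates of a group shared part of their peaks. The list of DMSO replicate 1 overlapped that of replicate 2 at 222 of its 669 peaks (33.2%), against 2.95% when peaks were shuffled within their genes. The share was 54.4% for SKBG-1(R), against 7.07% shuffled, and 54.3% for SKBG-1(S), against 3.58%. Shuffled peaks were spread evenly over a gene, while the real intronic peaks clustered towards its start, so chance overlap may be higher than these values. Lists of the same replicate number and different treatment overlapped by 40.5 to 64.7%, and lists that share neither number nor treatment by 26.8 to 66.9%. Both lists of a group held peaks in 188 genes for DMSO, 416 for SKBG-1(R) and 316 for SKBG-1(S), and 134 genes were bound in both lists of all 3 groups. The order of the groups depends on list length. With lists of equal size the genes were 108 for DMSO, 42 for SKBG-1(R) and 127 for SKBG-1(S), and the overlaps of replicates 27.4, 25.3 and 49.5%. Same-numbered lists of different treatment then overlapped by 25.9 to 52.5%, and lists that share neither by 21.1 to 41.3%. DMSO and SKBG-1(R) shared 150 genes bound in both lists, against 46.3 for independent sets among the 1689 genes with any peak. DMSO and SKBG-1(S) shared 158, against 35.2, and the 2 compounds 238, against 77.8. Independent sets take every gene as equally likely to hold a peak. Peaks were unevenly spread over genes: in DMSO replicate 1, 117 of 238 genes held 1 peak and MIRLET7BHG 58. Chance sharing may therefore be higher than these values.

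The first comparison asks what SKBG-1(R) did to NONO contacts relative to DMSO. The SKBG-1(R) lists were almost without peaks on a long transcript that held peaks in both DMSO lists. AFF3 (ENSG00000144218, chromosome 2 from 99545419 to 100142739), which encodes a nuclear protein of the AF4 family, held 17 and 31 peaks in the DMSO lists and 1 and 0 in the SKBG-1(R) lists, with a log2 fold change in peaks per 10000 of −4.51 (95% interval −6.55 to −2.48). The 11 other tested genes at least as long had a median of −1.10 and a lowest value of −2.80, and the 58 of at least 200 kb a median of 0.04. CCND1, which encodes the cell cycle regulator cyclin D1, held 56 and 169 peaks with SKBG-1(R) and 15 and 11 in DMSO, in lists of unlike length. Per 10000 peaks these were 286.7 and 113.8 against 224.2 and 29.9 (means of 200 and 127). DMSO replicate 1 thus stood above SKBG-1(R) replicate 2. The log2 fold change of CCND1 was 1.06 (limma unadjusted p = 0.346). Of the 140 regions present in both SKBG-1(R) lists and no other list, 18 lay in CCND1. None of these passed the test over all genes: limma, with Benjamini-Hochberg adjustment, called 0 of 479 tested genes, and 15 had an unadjusted p under 0.05 (8 higher, 7 lower) where chance gives 24.0. The smallest adjusted p was 0.067, of AFF3. The Cochran-Mantel-Haenszel test, which counts peaks and takes each as independent, called 69 genes (34 higher, 35 lower). Some alternatives called AFF3, among them widths of peaks summed in place of peaks and leaving out DMSO replicate 2, each with 1 gene called. Without SKBG-1(R) replicate 1, 23 genes were called and AFF3, at −5.20 with an adjusted p of 0.111, was not among them. All 23 had 10 to 96 peaks in SKBG-1(R) replicate 2 and 0 in every other list, SKBG-1(R) replicate 1 included, so that leaving out that list fixes the call. Over the limma settings that tested AFF3 its log2 fold change went from −6.62 to −1.92. Where each group kept 2 lists, its limma adjusted p went from 0.00966 to 0.767. The AFF3 peaks in DMSO had log2 enrichments of 3.00 to 4.32, where the minimum of the lists was 3. Under stricter limits AFF3 held fewer than 10 peaks and was not tested.

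Among the other genes with the smallest p that were lower with SKBG-1(R), peaks were absent from both SKBG-1(R) lists for SGCZ, which encodes a sarcoglycan (2 and 9 peaks in DMSO), and SRRM4, a neural splicing factor (6 and 3). PPP3CA, the catalytic subunit of calcineurin, held 6 and 25 peaks in DMSO and 6 and 2 with SKBG-1(R), at −2.52. The histone methyltransferase gene EHMT1 was at −2.15, with 10 and 35 against 7 and 22. PHF21B was at −2.37, LZTS2 at −2.05, PTPRN2, which encodes a phosphatase-like protein of secretory granules, at −1.91 and C22orf34 at −1.41. The genes that were higher were UNKL, which encodes a zinc finger protein (0 and 8 peaks in DMSO, 27 and 77 with SKBG-1(R), 3.04), ACTN4, the actin crosslinker alpha-actinin 4 (0 and 0 against 22 and 10, 3.00), and GATAD2A, a subunit of the NuRD chromatin complex (0 and 3 against 9 and 46, 2.48). TCF20, a transcriptional coregulator, followed at 2.41, SLC7A1, a transporter of cationic amino acids, at 2.37, CARS, the cysteinyl-tRNA synthetase, at 2.30, and PISD, which makes phosphatidylethanolamine in mitochondria, at 2.24. DLG5, a scaffold protein of cell junctions, and TRIB3, a stress-induced pseudokinase, were both at 2.17, and ANKRD11 was at 1.79. The fold change of a gene with 0 peaks in a group depends on the prior count and is no bound. The median tested gene was itself at 0.23, at 0.35 with TMM scaling and at 1.10 with no scaling (for SKBG-1(S) against DMSO 0.14, 0.11 and 0.21, and between the compounds −0.08, 0.10 and 0.75). Under no scaling C22orf34 turned to 0.34.

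**Figure D3:**
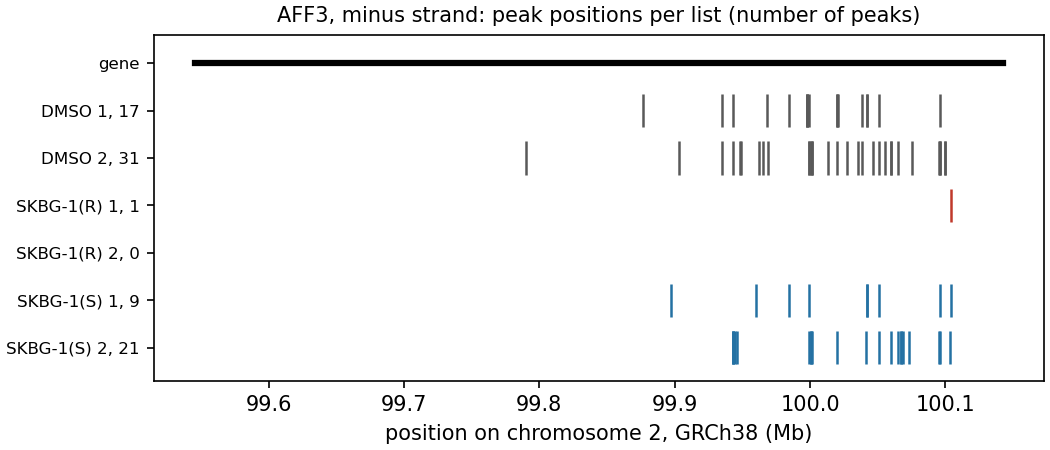
Midpoints of NONO peaks (vertical ticks) along AFF3 on chromosome 2, in megabases of GRCh38, with a line for each list and the number of peaks beside its name. The black bar is the gene. AFF3 holds 17 and 31 peaks in the DMSO lists and 1 and 0 in the SKBG-1(R) lists.

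The SKBG-1(R) lists are 2.92 and 4.04 times as long as those of DMSO, so more peaks in a gene need not mean a larger share of the list. FKBP5, a co-chaperone, held 1 and 2 peaks in DMSO and 3 and 0 with SKBG-1(R), and NCOA2, a transcriptional coactivator, 7 and 6 against 15 and 20. The pioneer-like factor GRHL2 held 1 and 9 against 3 and 12, the prostate transcription factor SPDEF 1 and 7 against 2 and 29, and ZBTB16 0 and 15 against 8 and 18. Of the neuroendocrine markers only SRRM4 had peaks, and it passed when adjusted over the list alone (limma adjusted p = 0.0195), which for a list with 1 tested gene is its unadjusted p. Paraspeckle proteins (6 tested: DAZAP1, RBM14, AHDC1, MATR3, SS18L1 and SMARCA4) had a median of 0.34 and a camera adjusted p of 0.813 (0.844 with an estimated correlation), with 2 and 15 peaks in DMSO and 7 and 71 with SKBG-1(R) for DAZAP1, and 2 and 5 against 2 and 2 for MATR3. Prostate cancer drivers (4 tested, ZFHX3, EGFR and EZH2 among them) were at −0.18, adjusted p = 0.785, and splicing factors (3 tested: HNRNPF, SRPK2 and PTBP1) at 0.42 with a mean of −0.07, adjusted p = 0.785. Lists with 2 tested genes had no set test. Of polyadenylation and transcription factors, BRD3 held 0 and 2 peaks in DMSO and 0 and 27 with SKBG-1(R). Of cell cycle genes, E2F3 held 3 and 5 against 12 and 11 beside CCND1, and of electrophile and heat stress genes TRIB3 held 0 and 1 against 9 and 13 and ATF3 0 and 0 against 1 and 5. In these 3 lists, as in the paraspeckle, driver and splicing lists, 0 genes passed either over all genes tested or adjusted over the list alone. Nuclear long noncoding RNAs had peaks in 5 of 28 listed and 0 tested. The snoRNA host genes, ribosomal proteins, replication-dependent histones, transcripts of the mitochondrial genome and markers of other cell types had 0 genes with a peak.

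The regions found in both SKBG-1(R) lists and nowhere else were led by CCND1, at chromosome 11 from 69650096 to 69650196 in a distal intron, where the authors' log2 enrichment was 4.53 and 5.0. The next 4 by the weaker list were also in CCND1 introns, between 69646532 and 69650965. After CCND1 came MIRLET7BHG with 9 such regions, PMEPA1 with 6, ANKRD11 with 5 and LARP1, a translation regulator, with 4. DMSO had 3 regions in both its lists and no other, in a distal intron of PPP3CA (chromosome 4 from 101276756 to 101276816), the 5′ UTR of SBNO2 (chromosome 19 from 1173656 to 1173792) and a distal intron of AFF3 (chromosome 2 from 99934621 to 99934742). The number in SKBG-1(R) ranked 4 among the 15 pairs of lists and that of DMSO 15, and with lists of equal size they were 17 and 20. Both DMSO lists and neither SKBG-1(R) list had peaks in 10 genes, among them SGCZ, SRRM4, the elongation factor ELL2, the splicing factor TRA2A and the phosphodiesterase PDE4D.

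The SKBG-1(R) lists held 8400 ± 9117 peaks (SD, n = 2) and the DMSO lists 2174 ± 2128 (n = 2). The ratio was 2.92 in replicate 1 and 4.04 in replicate 2, with a geometric mean of 3.43, and an exact two-sided permutation test gave p = 0.667, where 2 lists against 2 cannot give a p below 0.333. On the log2 scale the difference of 1.78 was 0.32 without SKBG-1(R) replicate 2 and 0.55 without DMSO replicate 1, and 3.24 and 3.01 without the other list of each group. The intronic share was 89.1% ± 1.82 with SKBG-1(R) and 89.3% ± 2.69 in DMSO (SD, n = 2 each; exact permutation p = 1), and the median intronic position differed by 0.015 (exact permutation p = 1).

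SKBG-1(S) was compared with DMSO in the same way. The genes with the smallest p were higher with the compound. UNKL held 0 and 8 peaks in DMSO and 24 and 24 with SKBG-1(S), a log2 fold change of 3.38 ± 1.04 (SE). TRIB3 held 0 and 1 against 8 and 8 (2.85 ± 1.10), ARHGEF2, which encodes a microtubule-bound guanine nucleotide exchange factor, 0 and 0 against 4 and 9 (2.80 ± 1.07), and GRB10, an adaptor of insulin receptor signalling, 0 and 3 against 8 and 12 (2.69 ± 1.06). The phosphatase gene PTP4A1 held 0 and 0 against 3 and 6, and CARS 0 and 0 against 2 and 8. By limma with Benjamini-Hochberg adjustment 0 of 479 genes passed, with a smallest adjusted p of 1. An unadjusted p under 0.05 was found for 6 genes, all higher, and the Cochran-Mantel-Haenszel test called 10 (ANKRD11, ARHGEF2 and UNKL higher, and BAHCC1, C22orf34, C7orf50, GSE1, PLEC, PMEPA1 and ZFPM1 lower). The median 95% half-interval of a gene, before adjustment, was 2.23 on the log2 scale. In lists simulated for SKBG-1(R) against DMSO, with 200 of 479 genes changed, only 35% of genes changed 16-fold were called. Those lists were drawn independently of each other, so this share is not the sensitivity for SKBG-1(S) and may be lower where few genes change. Both compounds are set against the same DMSO lists, so part of any excess common to the 2 may come from those lists.

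The other higher genes had log2 fold changes of 2.24 (ACTN4), 2.17 (ATXN1, which encodes ataxin 1), 2.10 (the long noncoding RNA LINC-PINT) and 1.94 (ACTB, which encodes beta-actin). The genes lower with SKBG-1(S) had larger p. SRRM4 was at −1.65, SGCZ at −1.52, the zinc finger factor CASZ1 at −1.51, RGS20, a regulator of G protein signalling, at −1.50, the small GTPase gene RAB40C at −1.39 and the kinase gene STK25 at −1.30. ZFHX3, a homeobox factor, was at −1.27, PMEPA1, which is induced by TGF-beta, at −1.20, and AFF3 at −1.19. Of these, CASZ1 turned to 0.12 under stricter limits and 0.18 without SKBG-1(S) replicate 1, PMEPA1 to 0.34 under stricter limits and ZFHX3 to 0.09 when widths of peaks were summed. AFF3 held 9 and 21 peaks with SKBG-1(S) against 17 and 31 in DMSO.

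No gene list passed with SKBG-1(S). Paraspeckle proteins had a median log2 fold change of 0.70 (5 of 6 members above 0, camera adjusted p = 0.278), prostate cancer drivers −0.20 (adjusted p = 0.590) and splicing factors 0.39 (adjusted p = 0.981), with 0 members passing adjusted over the list alone. In the electrophile and heat stress list TRIB3 passed when adjusted over the list alone (limma adjusted p = 0.0331), 1 gene of 2 tested, and ATF3, a stress-induced transcription factor, held 0 and 0 peaks in DMSO and 2 and 3 with SKBG-1(S). Of the 2 polyadenylation and transcription genes and the 2 cell cycle genes 0 passed either way, with 4 CCND1 peaks in SKBG-1(S) replicate 2 and 21 in replicate 1. SRRM4, the neuroendocrine marker, had a limma adjusted p of 0.169 over its list alone.

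Both SKBG-1(S) lists and no other shared 18 regions, among them an intron of the noncoding RP5-1103G7.4 on chromosome 20 (325279 to 325358), 1 of CUX1, a homeobox factor, on chromosome 7 (101922584 to 101922722), 1 of PTP4A1 on chromosome 6 (63572813 to 63572891), 1 of the pseudogene SUZ12P on chromosome 17 (30731627 to 30731700) and an intergenic site on chromosome 19 (13842201 to 13842255). A pseudogene can take reads from its parent gene, so the SUZ12P region is uncertain. The number of regions in SKBG-1(S) ranked 11 among the 15 pairs of lists, and with lists of equal size it was 25. Pairs that share neither replicate number nor treatment held 8 to 64 such regions in the full lists, so these sites are not shown to be particular to SKBG-1(S). The SKBG-1(S) lists held 2602 ± 1930 peaks (SD, n = 2), 1.85-fold the DMSO list in replicate 1 and 1.08-fold in replicate 2 (geometric mean 1.41, exact permutation p = 0.667). The log2 difference of 0.50 turned to −0.73 without DMSO replicate 1 and to −0.34 without SKBG-1(S) replicate 2, and was 1.73 without DMSO replicate 2 and 1.34 without SKBG-1(S) replicate 1. The intronic share was 89.7% ± 0.23 (SD, n = 2; exact permutation p = 1), and the median intronic position was lower by −0.028 (exact permutation p = 1).

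The stereoisomers were compared directly, at the same dose and time. AFF3 held 9 and 21 peaks with SKBG-1(S) and 1 and 0 with SKBG-1(R), a log2 fold change of SKBG-1(R) over SKBG-1(S) of −3.33 (95% interval −5.37 to −1.29). PPP3CA held 13 and 20 against 6 and 2 (−2.43, −4.54 to −0.32). CCND1 was on the other side, with 21 and 4 peaks for SKBG-1(S) and 56 and 169 for SKBG-1(R), at 1.88 (−0.41 to 4.17). None of these differences passed. Limma with Benjamini-Hochberg adjustment called 0 of 479 genes, with a smallest adjusted p of 0.995 and 5 genes, all lower with SKBG-1(R), at an unadjusted p under 0.05, and the Cochran-Mantel-Haenszel test called 89 (45 higher, 44 lower). Without SKBG-1(R) replicate 1 limma called the same 23 genes as against DMSO, which held 0 peaks in that list too, so the count carries no further evidence.

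TRIB3 held a mean of 27.4 peaks per 10000 with SKBG-1(R) and 42.4 with SKBG-1(S), and ATF3 4.2 and 11.9. With a half-interval of 2.23 log2 units at the median gene, a missed threshold does not show that the compounds act alike. Other genes lower with SKBG-1(R) than SKBG-1(S) were LZTS2 (−2.26), GNPTG, a subunit of the enzyme that tags lysosomal proteins (−2.22), PTP4A1 (−2.20), PKD1P6 (−2.03), the kinase gene TNK2 (−1.99), PHF21B (−1.96) and FGF13 (−1.83). PKD1P6 is a pseudogene of PKD1 and can share its reads, so its value is uncertain. Genes higher with SKBG-1(R) were DLG5 (1.85), FBXL18, an F-box protein gene (1.81), the histone demethylase gene PHF2 (1.78), DGCR2 (1.69), DUSP8, which encodes a MAP kinase phosphatase (1.67), PLEKHA6 (1.62), KIAA1671 (1.46), PMEPA1 (1.43) and FAM102A (1.35). Of the gene lists, paraspeckle proteins had a median of −0.69 (camera adjusted p = 0.552), splicing factors −0.25 (adjusted p = 0.757) and prostate cancer drivers 0.15 (adjusted p = 0.911). In these lists, and in the lists with 1 or 2 tested genes, 0 members passed over all genes tested or adjusted over the list alone.

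The SKBG-1(R) lists were longer than the SKBG-1(S) lists, 1.58-fold in replicate 1 and 3.74-fold in replicate 2 (geometric mean 2.43, exact permutation p = 0.667). The log2 difference of 1.28 rested on SKBG-1(R) replicate 2, without which it was −0.18, and was 2.74 without SKBG-1(R) replicate 1, 0.44 without SKBG-1(S) replicate 1 and 2.12 without SKBG-1(S) replicate 2. The intronic share differed by −0.63 percentage points and the median intronic position by 0.043 (exact permutation p = 1 for both).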

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

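All tests in this part were chosen after the result was seen. Peaks that the authors assign to no gene enter none of the gene comparisons, and a group of them on the minus strand of chromosome 19, from 13836816 to 13842828, stood above the control lists with SKBG-1(S). It lies within 10 kb of the microRNA genes MIR23A, MIR27A and MIR24-2 and of the annotated gene AC020916.1, all on the same strand. It held 7 and 13 peaks in the SKBG-1(S) lists, 20 in all, or 56.6 and 32.8 per 10000 peaks, against 0 and 7 peaks in DMSO, or 0.0 and 19.0 per 10000. The SKBG-1(R) lists held 5 and 20, or 25.6 and 13.5 per 10000. Replicate 1 of SKBG-1(R) was thus above both DMSO lists as well, and replicate 2 was not. With 2 lists per group, whether single lists stand out of their group was not tested.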

How the results depend on the processing

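The alternatives that reduce lists to equal size with the replicate number as a block, and stricter limits for gene lists, were chosen after the data were seen. Limma called 0 genes in every comparison, and most alternatives gave 0 as well. For SKBG-1(R) against DMSO, 1 gene (AFF3) was called with summed widths of peaks and 69 by the Cochran-Mantel-Haenszel test. Lists of equal size with a replicate block gave 7, which were AFF3, BCOR, GPR35, PHF21B and PTPRN2 lower and LINC-PINT and TRIB3 higher, and leaving out a list gave 0 to 23. For SKBG-1(S) against DMSO the counts were 10 by Cochran-Mantel-Haenszel and 1 (UNKL) with equal sizes and a replicate block. For SKBG-1(R) against SKBG-1(S) they were 89 by Cochran-Mantel-Haenszel and 0 to 23 when leaving out a list. The 23 genes, the same in both comparisons, held peaks in SKBG-1(R) replicate 2 alone and are called by construction without replicate 1. The Cochran-Mantel-Haenszel test takes peaks, not lists, as independent. It also compares lists within replicate numbers and uses no prior count, and which of these raises its count was not tested. No gene list passed camera under any alternative. By fry, which asks whether a list moves one way on balance and not whether it differs from other genes, paraspeckle proteins passed without DMSO replicate 2 (adjusted p = 0.0225 and 0.00585 for SKBG-1(R) and SKBG-1(S) against DMSO, 0.0161 between the compounds) and without DMSO replicate 1 between the compounds (0.0193).

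Lists with the same replicate number deviated together, with correlations of replicate 1 minus replicate 2 across 479 genes of 0.54 between DMSO and SKBG-1(R), 0.577 between DMSO and SKBG-1(S) and 0.422 between the compounds. The labels do not say that a number marks a shared batch. The correlations were taken on full lists, and replicate 2 was the longer list in every group. List length and a shared batch therefore cannot be told apart. With the replicate block 1 gene (AFF3) was called for SKBG-1(R) against DMSO, with a limma adjusted p of 0.00966 against 0.067 without the block. In the other comparisons 0 were called.

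Of 1017 values of the named genes under alternatives, 971 kept their direction and their side of the threshold, 41 passed it and 5 turned. The rule picked genes with a small p that moved the same way in both same-numbered pairs, so a kept direction is largely fixed by that choice. The block and the filters on peak number leave a gene's fold change as it was. Of the 41 that passed, 33 were from the Cochran-Mantel-Haenszel test. In 18 of the 1017 the Cochran-Mantel-Haenszel fold change was infinite and gives no value. Those that turned were C22orf34 with no scaling (0.34, SKBG-1(R) against DMSO) and, for SKBG-1(S) against DMSO, ZFHX3 with summed widths (0.09), PMEPA1 under stricter limits (0.34), and CASZ1 under stricter limits (0.12) and without SKBG-1(S) replicate 1 (0.18, the highest when leaving out a list, the lowest being −3.22). Of 1167 values of other list members, which stand in the text as numbers of peaks, 159 turned, 27 of them with no scaling and 19 without SKBG-1(R) replicate 2, so that their direction was not stable.

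Leaving out a list moved the log2 number of peaks from −0.73 to 1.73 for SKBG-1(S) against DMSO and from −0.18 to 2.74 for SKBG-1(R) against SKBG-1(S), and for SKBG-1(R) against DMSO from 0.32 to 3.24 without turning. The difference in intronic share went from −2.14 to 1.66, −1.52 to 2.29 and −1.92 to 0.66 percentage points for SKBG-1(R) and SKBG-1(S) against DMSO and for the compounds. With lists of equal size it was 0.90 for SKBG-1(R) against DMSO and 0.15 for the compounds, and under stricter limits −0.38 for SKBG-1(S) against DMSO and 0.29 for the compounds. The difference in intronic position went from −0.108 to 0.138, −0.095 to 0.039 and −0.08 to 0.166, and with a value per gene was −0.002 for SKBG-1(R) against DMSO. At equal sizes the position differed by 0.115, −0.042 and 0.157, in the same order of comparisons. The cause was not tested.

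Genes bound in both lists of DMSO, SKBG-1(R) and SKBG-1(S) were 55, 146 and 106 under stricter limits, 108, 42 and 127 with equal sizes and 83, 228 and 177 with at least 2 peaks in each list. Regions in both lists of DMSO and no other were 20 with equal sizes and 0 under stricter limits, and of SKBG-1(R) 17 and 58. Overlap of replicates was 5.2, 27.3 and 24.0% under stricter limits, 27.4, 25.3 and 49.5% with equal sizes and, for SKBG-1(R), 52.1% where 50% of the shorter peak must overlap. What depth limits stays open, since read totals are unknown.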

Other observations

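The test of transcript GC was set before its result was seen, and all other tests in this part were chosen after; the idea of GC came from the names of the 23 genes called without SKBG-1(R) replicate 1. Peaks more than 100 kb from the start of their gene made up 6.2 and 9.6% of the intronic peaks in DMSO, 2.5 and 7.1% with SKBG-1(R) and 3.4 and 8.3% with SKBG-1(S). Without AFF3 they were 3.7 and 9.1%, 2.5 and 7.1%, and 2.9 and 8.1%, so that 1 gene carries much of the difference in replicate 1. In lists of equal size, AFF3 included, they were 6.2 and 5.5%, 0.7 and 1.4%, and 1.7 and 4.7%.

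AFF3 was almost without peaks in the SKBG-1(R) lists, which were the longer ones within each replicate number and held 1 of its 49 peaks in these groups. It was picked for this count, which therefore tests nothing further. Gene length cannot be told apart, since the other 11 tested genes at least as long had a median log2 fold change of −1.10 (bootstrap interval −1.80 to 0.21, SD 1.26), with a lowest of −2.80, while the 58 of at least 200 kb had a median of 0.04. Chance among the tested genes cannot be told apart from an effect either, as 2 lists per group are few and the limma adjusted p depended on the setting. It was 0.067 in the main fit, 0.00966 with the replicate number as a block and 0.767 with no scaling. The labels do not tie the replicate number to a batch. Whether SKBG-1(R) lowers this RNA or its NONO contacts stays open, since RNA levels are not analysed here.

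Among the genes with more peaks with the compounds, 5 (TRIB3, ATF3, CARS, GRB10 and ARHGEF2) were noticed as genes that the stress-response factor ATF4 is known or reported to induce. They held 4 peaks in the 2 DMSO lists and 163 in the 4 lists of the compounds, which hold more peaks in all. By replicate these were 0 of 669 and 4 of 3678 peaks in DMSO. With SKBG-1(R) they were 26 of 1953 and 73 of 14847, and with SKBG-1(S) 24 of 1237 and 40 of 3967. They were picked for these counts, so a test on them would restate the choice. A hypothesis of ATF4 induction predicts the same of its other targets, but of 47 others listed only 8 had a peak (SLC7A5, SLC7A1, SLC6A9, SESN2, GPT2, EIF4EBP1, TNFRSF10B and SQSTM1), and the classic targets ASNS, CHAC1, DDIT3, DDIT4 and SLC7A11 had none. These 8 others held 60 peaks in the DMSO lists and 388 in those of the compounds, which hold more peaks in all. All 60 in DMSO were in SLC7A5 (10 and 50). It also held 12 and 225 of the 26 and 248 peaks with SKBG-1(R), and 30 and 72 of the 33 and 81 with SKBG-1(S). The 8 others had a median log2 fold change of 0.27 with SKBG-1(S). That stood at percentile 93.4 of 10000 random lists matched on number of peaks, short of the 95 set for the test. For SKBG-1(R) the percentile was 97.0 against DMSO and 98.4 against SKBG-1(S). As the test was set on SKBG-1(S), and SKBG-1(R) would reach the limit, induction and chance cannot be told apart.

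The list of SKBG-1(R) replicate 2 was the longest, at 14847 peaks. More immunoprecipitated reads per input read do not account for it, as its ratio, 3.12, lay between 2.96 and 3.23 of the other replicate 2 libraries. Deeper sequencing of the same sites cannot be told apart, as it overlapped 63.5% of the DMSO replicate 2 peaks, less than the 90% set for the test. That is more than the 40.5% of SKBG-1(S) replicate 2, but a longer list overlaps more by its length. Shuffled peaks gave 10.02% for SKBG-1(R) and 3.01% for SKBG-1(S). With lists of equal size the order turned, at 25.9 and 46.2%. Across 479 genes, which are not independent replicates, the peak density of SKBG-1(R) replicate 2 relative to the other replicate 2 lists was higher in genes with GC-rich transcripts (Spearman rho 0.46, bootstrap interval 0.38 to 0.53). Without the 23 genes that gave the idea the rho was 0.43 (0.35 to 0.50). GC was that of the longest annotated transcript without introns, whereas 90.4% of the peaks of this list were intronic. The GC of the peaks themselves was not measured. The like difference in density in replicate 1 had a rho of −0.13 (−0.22 to −0.04), and density alone was lower in GC-rich genes in all 3 replicate 1 lists (−0.21 in DMSO, −0.35 with SKBG-1(R), −0.18 with SKBG-1(S)). In replicate 2, density alone had a rho of 0.46 with SKBG-1(R), 0.04 in DMSO and −0.11 with SKBG-1(S). A GC bias of the SKBG-1(R) replicate 2 library is a candidate explanation, and an effect of SKBG-1(R) is not excluded.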
